A study of Mus musculus with 12 samples.

How the data were processed

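Total RNA from 12 samples of J1 mouse embryonic stem cells was measured on Agilent one-colour (Cy3) arrays, in 4 groups of 3 samples. Samples given vitamin C (VC) and their water controls (ddH2O) were on one array design, and samples given retinoic acid (RA) and their solvent controls (DMSO) were on another. The designs were normalized and fitted separately, and no level was set across them. The labels do not say whether the 3 samples of a group came from separate cultures. Except for overlaps, p-values therefore rest on the spread between these samples, which may be technical.

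The deposited scanner files hold an intensity per spot, background-subtracted and detrended within the array by Agilent Feature Extraction 10.7.3.1, per the file headers. The submitters' processing notes name version 10.7. The deposited series tables hold log2 values per probe. Set against the log2 scanner signal of the same array they had slopes from 0.977 to 1.079, with a column median of 5.96 in each VC and ddH2O column and of 5.184 in each RA and DMSO column. Their distributions were nearly identical between the arrays of a design. The step that produced this is not given in the sources used here. Quantile normalization of the log2 scanner signal gave nearly the same values. On the VC and ddH2O arrays r was 1, with mean absolute differences of 0.001 to 0.002. On the RA and DMSO arrays r was 0.99999, with mean absolute differences of 0.182 to 0.183. Quantile normalization and the authors' series values, used below as alternatives, are therefore not independent checks.

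For the comparisons, log2 of the processed intensity was taken and the 75th percentile of each array's non-control spots was subtracted. Spots flagged as outliers were left out and the spots of a probe were averaged. The files hold an accession for each probe and no gene name. Accessions, without versions, were matched to gene symbols through a RefSeq gene table for GRCm38.p6, which was used for names alone. On the VC design 27479 of 41174 probes matched, giving 18749 genes, and on the RA design 27235 of 55681 probes, giving 20660 genes. This replaced the gene name column that the design fixed in advance had assumed. A gene was represented by its brightest probe, and it was tested if that probe was well above background on at least 3 of the 6 arrays. No spot was saturated. The number of arrays limits the precision.

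Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fixed gene lists, 35 in all and including markers of fibroblasts and of blood and endothelium, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Overlaps were tested with a two-sided Fisher's exact test. Where a gene was not well above background on any array of one group in any of its probes, the fold is given as a lower bound, the bright group's mean against, per array, the higher of the lowest signal well above background and the gene's own signal.

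The lists, the comparisons, the main settings and the rule for named genes were fixed before the data were examined. The rule took 16 set genes, the 8 largest rises and 8 largest falls among called genes with arrays that did not overlap, up to 2 rises and 2 falls of each list, and up to 4 genes for each pattern of calls in both comparisons. Accession-like and clone names were passed over. One set gene is not reported here.

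On simulated data with the real means and spreads and 200 changed genes, the VC fit over 14499 genes recovered 68.7% of 1.5-fold changes, 89.6% of 2-fold changes and 96.7% of 4-fold changes, and 6.1% of its calls were false. The RA fit over 16002 genes recovered 54.3%, 78.2% and 94.5%, and 4.8% of its calls were false. The simulated noise was independent between genes and held no slide effect. Far fewer genes changed than were called in VC or RA, so these rates need not hold for the real data. In VC the median size of a called change was 0.382 log2, smaller than the smallest simulated change of 1.5-fold.

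The alternatives were other normalizations, background corrections, filters, probe summaries, variance models, thresholds, blocks and each sample left out in turn. The mean signal column was not used here, so the normexp correction ran on the median signal and its local background. That planned fit gave background means of -303.1, -379.5 and -857.4 on ddH2O replicate 2, VC replicate 1 and VC replicate 2, against values between -6.467 and -1.837 on the other arrays. Those 3 arrays held 7, 5 and 13 spots with a local background over 10 times the array's median, up to 59239 on VC replicate 2. The planned values are kept, and a fit without such spots was added after seeing the data. It still gave -21.67 on ddH2O replicate 2.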

Results

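The series measured gene expression in J1 mouse embryonic stem cells, a pluripotent line kept here on gelatin with 1000 U/mL of leukaemia inhibitory factor (LIF), the cytokine that holds mouse stem cells undifferentiated. Cells received VC, its ddH2O control, RA at 1 µM or its DMSO control for 24 h, with 3 samples in each group. The question, from the series title, was which genes vitamin C and retinoic acid regulate in these cells. Between 67% and 70.3% of probes were well above background on the VC and ddH2O arrays, and between 60.9% and 65.6% on the RA and DMSO arrays. Correlations across probes representing genes were between 0.9949 and 0.9974 within the VC and ddH2O groups and between 0.9919 and 0.9976 within the RA and DMSO groups. From a VC to a ddH2O array they were between 0.9925 and 0.9955, which overlapped the range within groups. From an RA to a DMSO array they were between 0.8983 and 0.9033.

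Many genes differed between VC and ddH2O, mostly by small amounts. Srxn1, an antioxidant enzyme gene, was 1.80-fold higher in VC than in ddH2O (log2 difference 0.85, SE 0.05, limma adjusted p = 0.003133), and Apoe was 1.76-fold higher. Flt1, a VEGF receptor gene, was 2.64-fold lower (log2 difference -1.40, SE 0.07, limma adjusted p = 0.003133), and Egr1, an immediate early transcription factor, was 2.24-fold lower. The smooth muscle genes Myl9 and Tagln were 2.38-fold and 2.28-fold lower, while Acta2, the smooth muscle actin gene, was 1.23-fold higher on its brightest probe, with other detected probes from -0.18 to 0.51. Fgf10 was at least 2.67-fold lower, since it was not well above background on any VC array. Of 14531 genes tested, 931 were higher and 1521 lower, and 2 of the former and 39 of the latter changed at least 2-fold.

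**Figure D1:**
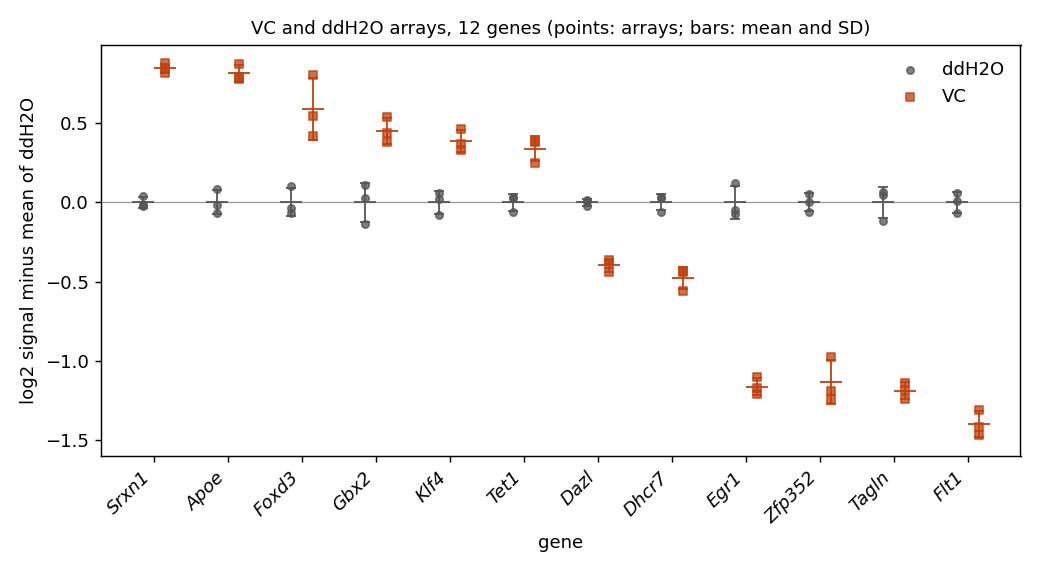
Log2 signal of 12 genes on each VC and ddH2O array, minus the gene's ddH2O mean; points are arrays and bars the mean and SD of 3 arrays. Srxn1 lay 0.85 above its ddH2O mean and Flt1 lay at -1.40.

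Some pluripotency genes were higher in VC. Of 15 naive pluripotency genes tested, 6 rose and 1 fell (10 and 1 adjusted over the list alone), with a median log2 difference of 0.26 (adjusted p = 0.000471, and adjusted p = 0.328 with an estimated correlation). Tcl1 was 1.41-fold, Gbx2 1.37-fold and Klf4 1.31-fold higher. Dppa3 was the member that fell, by 0.30 on the log2 scale. In the authors' series values it lay at 0.182 and did not pass the test (limma adjusted p = 0.776). Spots flagged as outliers were left out in the main setting, but nothing was left out of the series values. Whether a flagged spot gave the difference for Dppa3 was not tested. Of 12 general pluripotency genes 4 rose, among them Foxd3, 1.51-fold, and Sall4, 1.36-fold (6 adjusted over the list alone; list adjusted p = 0.00178, and adjusted p = 0.328 with an estimated correlation). Of 15 LIF and STAT3 targets 6 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0062, and adjusted p = 0.328 with an estimated correlation). Socs2 was 1.41-fold higher. Pou5f1 (0.02, SE 0.10), Sox2 (0.16, SE 0.07), Socs3 and Stat3 did not pass the test, and no probe matched Nanog on this design.

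Of 18 NRF2 and antioxidant genes, 7 rose and none fell (8 adjusted over the list alone; adjusted p = 2.13e-05, and adjusted p = 0.148 with an estimated correlation), including Gpx2 at 1.52-fold. Of 19 cholesterol synthesis genes, 11 fell and none rose (14 adjusted over the list alone; adjusted p = 9.05e-06, and adjusted p = 0.148 with an estimated correlation). The sterol carrier gene Stard4 fell by 0.58 on the log2 scale and Dhcr7, the last enzyme of the pathway, was 1.39-fold lower. Of 10 genes of the 2-cell stage, 7 fell (8 adjusted over the list alone; adjusted p = 9.05e-06, and adjusted p = 0.286 with an estimated correlation), with Zfp352 2.19-fold and Tcstv3 1.87-fold lower. Several members of that list, such as the Usp17l and Zscan4 genes, belong to families of similar copies, and cross-hybridisation among them was not tested.

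Of 17 retinoic-acid-responsive genes 6 fell (10 adjusted over the list alone; adjusted p = 0.000569, and adjusted p = 0.154 with an estimated correlation). Foxa1 was 1.73-fold lower. Interferon response genes fell in 5 of 13 (6 adjusted over the list alone; adjusted p = 0.00289), germline genes in 6 of 24 (adjusted p = 0.0062), with Dazl 1.32-fold lower, and neuroectoderm genes in 5 of 16 (adjusted p = 0.00686), with the Notch ligand gene Dll1 1.82-fold lower. With an estimated correlation these 3 lists had adjusted p = 0.192, 0.286 and 0.320. Adjusted over the list alone the germline and neuroectoderm counts were the same. Immediate early and heat shock genes fell in 5 of 14 (7 adjusted over the list alone; adjusted p = 0.0267, and adjusted p = 0.286 with an estimated correlation). Primitive streak and mesoderm genes fell in 2 of 11 and rose in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.0476, and adjusted p = 0.328 with an estimated correlation).

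The other 23 lists did not pass the test in VC. Among 16 genes of the DNA methylation and TET machinery 2 rose, Zfp57 by 1.67-fold and Tet1, a 5-methylcytosine dioxygenase, by 1.26-fold (log2 difference 0.34, SE 0.06). Tet2 did not pass (0.07, SE 0.09). Of 14 fibroblast markers 4 fell and 1 rose (list adjusted p = 0.13). None of 8 blood and endothelial markers was called. Falls outnumbered rises over all 14531 genes tested, at 1521 against 931. The same was seen among imprinted genes (4 of 18), primitive endoderm genes (5 of 18), trophectoderm genes (5 of 14, with 1 higher), ER stress genes (5 of 19), Wnt targets (4 of 11), collagen genes (3 of 18) and retinoid metabolism genes (3 of 15). The lists of hypoxia targets, p53 targets, glycolysis, Hox paralogs, BMP targets, Nodal targets, FGF feedback, primed epiblast, histone demethylases and both cell cycle phases held between 0 and 3 called genes each, and no gene of the mitochondrial respiratory chain was called.

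The arrays lay on 3 slides. One slide held ddH2O replicates 2 and 3 with VC replicates 1 and 2, and VC replicate 3 was scanned on another day. With the slide as a block, which equals the fit within the shared slide, limma called 0 genes, and 3848 had an unadjusted p under 0.05. Of those, 88.8% had the same sign between the remaining VC array and the remaining ddH2O array, which were on separate slides. Across all genes, not only those selected, Pearson's r between both estimates was 0.47. The VC counts also moved with single samples: without ddH2O replicate 2 there were 61 genes higher and 340 lower, without VC replicate 1 there were 124 and 502, without ddH2O replicate 1 there were 170 and 564, and without VC replicate 3 there were 379 and 919. Without VC replicate 2 there were 553 genes higher, and without ddH2O replicate 3 there were 975 lower. The planned normexp background correction called 0 genes, with 297 at an unadjusted p under 0.05, after its fit failed on 3 arrays, and 371 were higher and 614 lower when spots of very high local background were left out, a fit that still stood apart on ddH2O replicate 2 (background mean -21.67). With slide as a random block 1024 genes were higher and 1632 lower. The balance of calls depended on the scaling: rises were 38% of calls in the main setting, 48% with median scaling and 59.5% with spike-in scaling.

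Most genes differed between RA and DMSO, and many by large amounts. Cyp26a1, the enzyme that degrades retinoic acid, was 323-fold higher in RA than in DMSO (log2 difference 8.33, SE 0.08, limma adjusted p = 5.066e-08), and its relative Cyp26b1 was 986-fold higher. Hoxc9 and Hoxd4 were at least 328-fold and 339-fold higher, as neither was well above background on any DMSO array. The stem cell factors Pou5f1 and Klf4 were 33-fold and 29.3-fold lower, and Otx2 and Fgf4 were 152-fold and 131-fold lower. Of 16015 genes tested 5738 were higher and 6753 lower, and 2791 and 2415 changed at least 2-fold. All DMSO arrays were on one slide and all RA arrays on another, so this fit cannot tell slide and treatment apart.

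**Figure D2:**
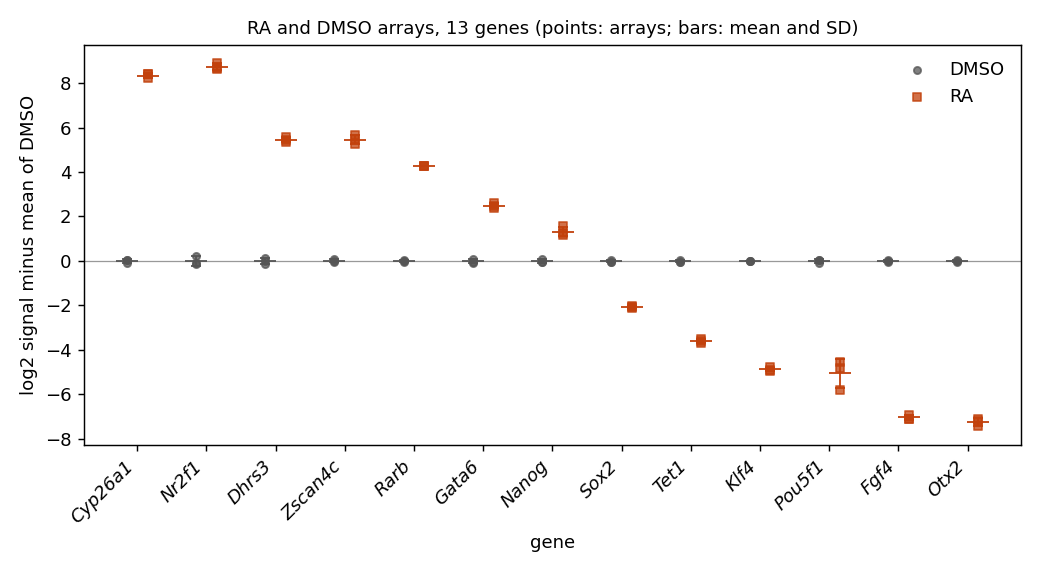
Log2 signal of 13 genes on each RA and DMSO array, minus the gene's DMSO mean; points are arrays and bars the mean and SD of 3 arrays. Cyp26a1 lay 8.33 above its DMSO mean and Otx2 lay at -7.25.

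All 21 retinoic-acid-responsive genes tested rose, with a median log2 difference of 5.45 (adjusted p = 4.79e-11, and adjusted p = 0.0532 with an estimated correlation). Rarb was 19.3-fold, Dhrs3 43.8-fold and Crabp2 50.1-fold higher. Stra8 was 2.59-fold higher. All 15 tested Hox genes of paralogs 1 to 5 rose (adjusted p = 5.23e-09), and of paralogs 6 to 13 there were 13 higher and 1 lower, Hoxb13 (adjusted p = 8.29e-05). Both had adjusted p = 0.0532 with an estimated correlation. Of 16 retinoid metabolism and receptor genes 14 rose and 2 fell, the receptors Rarg, 12.7-fold, and Rara, 1.74-fold (list adjusted p = 8.29e-05, and adjusted p = 0.0838 with an estimated correlation).

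Of 18 naive pluripotency genes 16 fell and 1 rose (median -4.01, adjusted p = 1.32e-06, and adjusted p = 0.0532 with an estimated correlation). Tcl1 was 116-fold lower. The member that rose was Nanog, 2.50-fold higher (log2 difference 1.32, SE 0.12, limma adjusted p = 9.279e-05), from the one probe that matched it. Of 13 general pluripotency genes 12 fell, and Lin28a rose 1.34-fold (list adjusted p = 7.23e-05, and adjusted p = 0.0532 with an estimated correlation). LIF and STAT3 targets fell in 12 of 15 (adjusted p = 0.00109, and adjusted p = 0.189 with an estimated correlation), with Socs3 at a log2 difference of -2.00, while Stat3 did not pass (0.03, SE 0.08; its other detected probe lay at -0.41). Nodal targets fell in 9 of 11 and rose in 1 (adjusted p = 0.00226, and adjusted p = 0.0838 with an estimated correlation), with Lefty1 22.4-fold lower. Tet1 was 12.1-fold and Tet2 5.55-fold lower, in a list of 16 where 10 fell and 4 rose (adjusted p = 0.0843).

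Of 18 genes of the 2-cell stage 17 rose (median 4.88, or 4.21 with genes at their bounds; adjusted p = 2.98e-07, and adjusted p = 0.0532 with an estimated correlation). Zscan4c was 44.0-fold and Tcstv1 41.6-fold higher. The member that was not called was Zfp352 (-0.14 on its brightest probe, while its other detected probe lay at 5.59), singled out here after its value was seen. Several lineage lists also rose: primitive endoderm in 17 of 21, with 2 lower (adjusted p = 3.02e-05), with Gata6 5.56-fold higher, neuroectoderm in 16 of 21, with 5 lower (adjusted p = 0.00215), with Irx3 89.4-fold higher, trophectoderm in 11 of 16, with 4 lower (adjusted p = 0.00936), with Gata3 29.5-fold higher, and BMP targets in 7 of 11, with 2 lower (adjusted p = 0.0311). With an estimated correlation these had adjusted p = 0.116, 0.0838, 0.096 and 0.21. Of 11 primitive streak and mesoderm genes 4 rose and 4 fell (list adjusted p = 0.483). Collagen genes rose in 15 of 19 and fell in 2 (adjusted p = 0.00011), imprinted genes rose in 15 of 19 and fell in 3 (adjusted p = 0.000261) and fibroblast markers rose in 12 of 14 and fell in 2 (adjusted p = 0.000149). With an estimated correlation these 3 lists had adjusted p = 0.0532, 0.087 and 0.0838. Col1a2 was 68.5-fold, Igf2 27.9-fold and Acta2 70.6-fold higher. p53 targets rose in 10 of 16 and fell in 4 (11 and 4 adjusted over the list alone; adjusted p = 0.0499, and adjusted p = 0.153 with an estimated correlation).

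Lists of growth and metabolism genes also fell. The respiratory chain fell in 20 of 21 (median -0.70, adjusted p = 8.29e-05), G1/S genes in 15 of 16 (adjusted p = 0.00109), G2/M genes in 12 of 15 (adjusted p = 0.0124), glycolysis in 16 of 19 (adjusted p = 0.00226), cholesterol synthesis in 16 of 19 (adjusted p = 0.00435), ER stress genes in 14 of 19 (adjusted p = 0.00387), hypoxia targets in 13 of 18 (adjusted p = 0.00154) and histone demethylases in 10 of 15 (adjusted p = 0.0303). In that order, 0, 1, 1, 2, 1, 1, 1 and 1 genes of these lists rose, and the lists had adjusted p = 0.0589, 0.184, 0.0962, 0.304, 0.155, 0.0838, 0.0962 and 0.125 with an estimated correlation. Pfkp was 19.2-fold lower on its brightest probe, while its other detected probe lay at -0.55, and Pdk1 was 13.4-fold lower. Adjusted over the list alone, the counts of every RA list but that of p53 targets were unchanged. No list kept its call in either comparison with an estimated correlation, and the lowest adjusted p was 0.0532 in RA and 0.148 in VC. Some estimates lay above the preset 0.01, such as 0.224 for naive pluripotency in VC. Others lay below it, such as 0.005 for retinoic-acid-responsive genes in RA and -0.028 for cholesterol synthesis in VC. For the latter lists a higher correlation was not what removed the call. The lists of primed epiblast, germline, NRF2, interferon, immediate early, primitive streak, FGF feedback, Wnt and blood and endothelial genes did not pass in RA. Another scaling moved the median of all genes in RA by -0.197 (median scaling) or -0.383 (spike-in scaling), and rises were then 36.8% or 28.8% of calls, against 45.9% in the main setting.

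**Figure D3:**
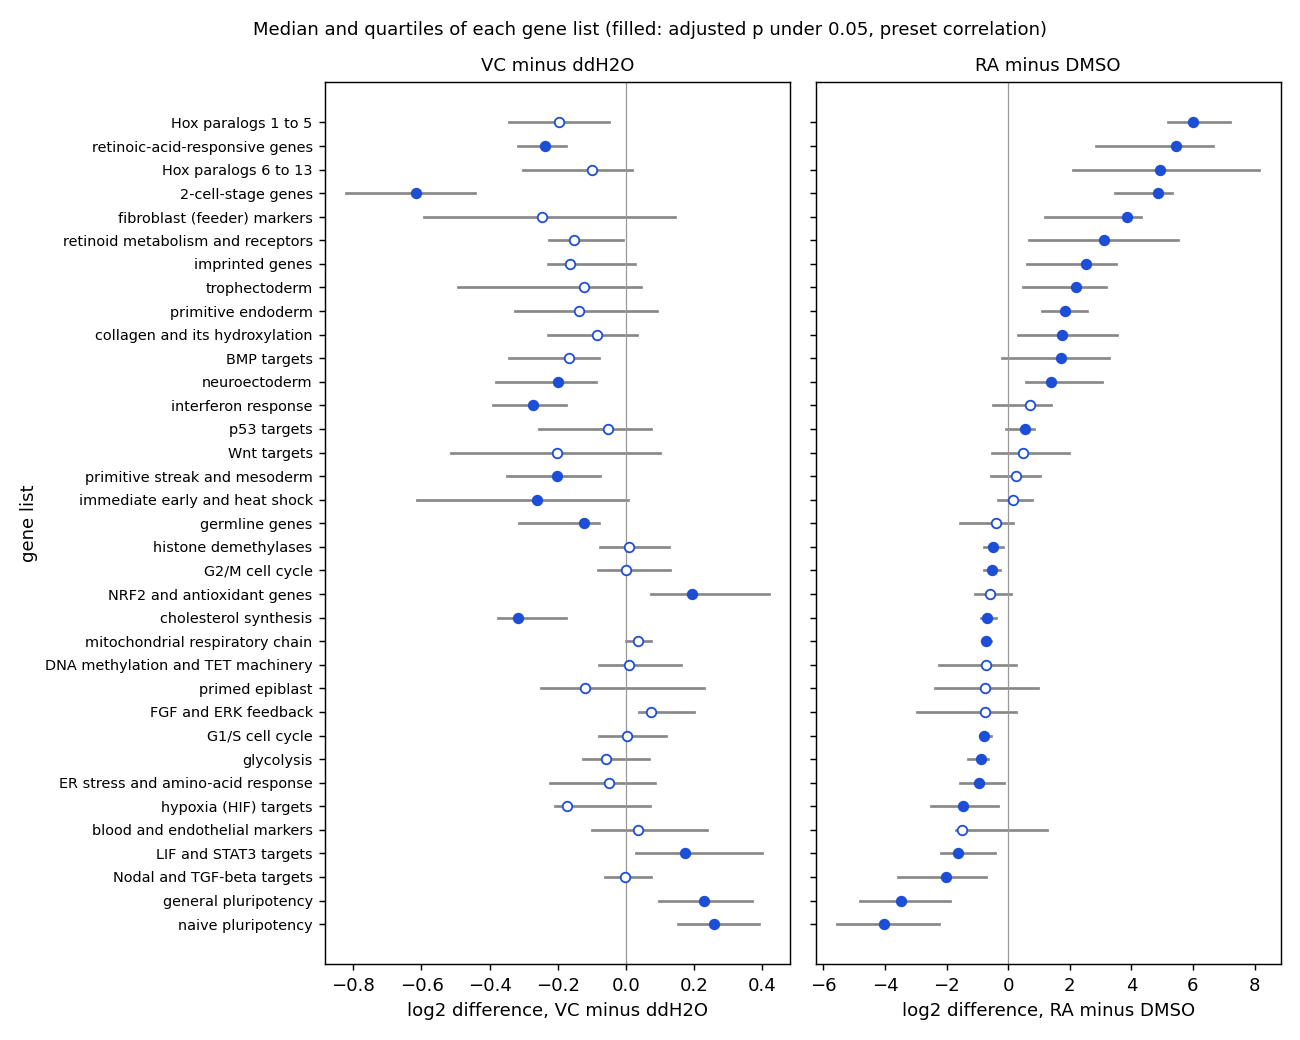
Median log2 difference of each gene list (points) with its quartiles (lines), VC minus ddH2O on the left and RA minus DMSO on the right, on different axes; filled points passed the test at the preset correlation. The 2-cell-stage list lay at -0.617 in VC and at 4.88 in RA.

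The comparisons shared no control sample, and 13728 genes were tested in both. Calls in both comparisons ran mostly in opposite directions. There were 777 genes lower in VC and higher in RA, against 473 for independent lists (odds ratio 2.68, Fisher's exact adjusted p = 1.34e-67), and 537 higher in VC and lower in RA, against 412.6 (odds ratio 1.81). The same direction was seen in 609 genes, against 954.7. Fisher's exact test counts genes as independent, which they are not, so its p does not measure the spread between samples. Flt1 and Cacna1g were lower in VC and 5.41-fold and 11.1-fold higher in RA, and Apoe and Zfp57 were higher in VC and 2.67-fold and 6.62-fold lower in RA. The other detected probe of Zfp57 lay at -0.01 in RA. That of Cacna1g lay at -0.36 in VC and at 4.56 in RA, and that of Flt1 at -1.72 in VC. Insyn1 and Endov were higher in both, though a probe of Endov lay at 0.07 in VC. Aoc3 was lower in both, as was Hlf, which turned to 0.149 in RA with either normexp fit and to 0.564 in VC with the planned one. Across genes, which are not independent replicates, Pearson's r was -0.215 and Spearman's rho -0.186. The count of 609 fell to 89 without ddH2O replicate 2, 136 without VC replicate 1, 171 without ddH2O replicate 1 and 318 without VC replicate 3, and to 0 with the slide block, where r was -0.193. The count of opposite calls, 1314 in the main setting, fell in the same order to 234, 359, 413 and 692, and to 0 with the slide block. With the planned normexp correction, whose fit failed on 3 VC and ddH2O arrays, both counts were 0 and r was 0.356. Without spots of high local background 229 calls had the same and 606 the opposite direction, and r was -0.263.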

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

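All tests in this part but those on the slides without both groups, on the trend with signal level and on other splits were chosen after the result was seen. Probes that matched no gene symbol were outside the comparisons and also carried signal: 149 were higher and 215 lower in VC than in ddH2O, and 6345 were higher and 4524 lower in RA than in DMSO. Among the latter, 3738 of the higher and 2198 of the lower probes were placed by chromosome region.

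The first pattern is the breadth of the RA response, 12491 of 16015 genes. Slide and treatment coincided there. Of 10 spike-in probes, which carry no treatment, 8 were above background on every array and lay at most 0.228 log2 from their own median. On the scale of the gene values those 8 were higher in RA by a median of 0.356 (0.173 to 0.585). Their mean on that scale was 4.224, 4.146 and 4.667 on RA replicates 1 to 3, and 3.913 to 3.988 in DMSO. The shift was thus largest on RA replicate 3. The arrays' 75th percentiles were 286.8 to 387.8 in RA and 605.6 to 609.1 in DMSO. The 2 other spike-ins, well above background on at most 1 array, lay up to 1.479 from the median difference of those 8. For the 2996 genes changed at least 2-fold whose group means both reached the dimmest of the 8, this argues against labelling or hybridisation as the whole cause. For the 6299 such genes changed under 2-fold the lower quartile of the changes was 0.372, below the highest spike-in difference, and it was raised by the calling itself. For those, and for the 2210 and 986 genes dimmer in a group, slide and treatment cannot be told apart. Of the genes changed at least 2-fold, at least 98.9% kept direction and call under each scaling tried. The largest shift of the median of all genes among these scalings was -0.383 (spike-in scaling). That is under the 1 log2 by which the genes were chosen, so direction was largely set in advance. The values show only that the scalings tried differ too little to give changes of this size. The list of retinoic-acid-responsive genes, fixed in advance, had a median of 5.451, as a response to RA would give. Any difference in culture or extraction, which spike-ins do not see, stays open.

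The second pattern is Nanog, higher in RA while Pou5f1, Sox2 and Klf4 were lower. Its lowest difference over the scalings was 0.937 (spike-in scaling), which argues against the choice among the scalings tried as the cause. A probe reading a near-identical copy could also give the rise, and with 1 matched probe it cannot be told apart from a change in Nanog itself.

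The third pattern is the opposition of the VC and RA changes. Across genes r was -0.193 within the slide that held both VC and ddH2O arrays, and -0.154 after the trend of each comparison with mean signal was removed. These argue against a slide difference among the VC and ddH2O arrays and against signal level as the whole cause. The single VC and single ddH2O array off that slide gave -0.181, but they lay on 2 slides, so they cannot settle whether the pattern rests on the arrays of the shared slide. Of all settings, r was positive only with the planned normexp correction, at 0.356, where the fit failed on 3 arrays. What underlies the pattern stays open.

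In each comparison 1 of the 10 splits of the 6 samples, the real one, gave as many called genes, and the highest other split called 0; with 10 splits a share under 0.05 cannot be reached. For gene lists the real split gave 12 in VC, against 7 at most elsewhere, and 25 in RA, against 23 at most elsewhere. List calls at the preset correlation thus also arose in splits that mixed the groups. A mixed split still held unequal numbers of treated samples on its sides. Part of the treatment difference remained between its sides and part went into its spread. Neither its list calls nor its lack of called genes shows what arises without a treatment effect. For the genes called in both comparisons in the same direction, 1 of 100 combined splits, the real one, gave as many (609), and the highest other gave 0. Splits that mixed the groups called 0 genes in their own comparison, so no combined split holding one could share a call, and this count decides nothing.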

How the results depend on the processing

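The slide as a random block, the spike-in scaling, the test of each probe on its own and the normexp fit without spots of high local background were chosen after seeing the data; the other alternatives were planned. In RA, every count kept within 1.5 times its main value under every alternative but those named here. Of the named RA genes and lists, most kept direction and call. The VC counts depended on the setting far more, and most lost calls of named VC genes came with a block or with a sample left out. Signal near background limits the genes given as bounds. Causes were not tested unless stated.

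In VC, 2 genes were higher and 39 lower at a 2-fold minimum, and 53 and 302 at an adjusted p under 0.01. Without a filter on dim probes 276 were higher and 676 lower. More genes were higher with the trend and robust variance model (1542), array weights (1514) and spike-in scaling (1504). With the slide block 0 were higher and 0 lower, at 3848 with an unadjusted p under 0.05, in a fit with fewer residual degrees of freedom. With an estimated correlation 0 lists were called in VC and 0 in RA. In RA, 2791 genes were higher and 2415 lower at a 2-fold minimum, and spike-in scaling gave 3139 higher. Each probe tested on its own gave 13322 higher and 13189 lower, over more features.

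The planned normexp background correction called 0 genes higher and 0 lower in VC, with 297 at an unadjusted p under 0.05, and 0 genes in both comparisons. Its fit failed on 3 arrays, where 5 to 13 spots of 45018 had a very high local background. Without such spots 371 genes were higher and 614 lower, and 229 were called in both comparisons in the same direction. That fit still gave a background mean of -21.67 on ddH2O replicate 2, against -6.262 to -2.867 on the other VC and ddH2O arrays. The reversals under the planned fit are given as measured. In VC the fit without such spots turned the test direction of the Nodal and TGF-beta targets list alone.

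Same-direction calls in both comparisons, 609 in the main setting, were 60 at a 1.5-fold minimum in both, 227 without a filter, 946 with array weights, 398 with spike-in scaling and 0 with the slide block. Leaving out one sample at a time gave 89 to 625 of them. It gave 61 to 747 genes higher and 340 to 1198 lower in VC, with 10 to 14 lists, and 5277 to 5883 higher and 6199 to 6924 lower in RA, with 23 to 25 lists.

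With the replicate block, 256 genes were higher and 652 lower in VC, and 206 were called in both comparisons in the same direction. Deviations of same-numbered samples correlated at -0.116, 0.06 and -0.066 in VC and at -0.036, -0.003 and -0.055 in RA, so the numbers do not pair the samples. With the block the test direction of the Nodal and TGF-beta targets list turned in VC, while its median stayed at -0.002.

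Directions that turned in VC are given as log2 differences, for a list as its median, where the direction is that of the test. A list can therefore turn while its median keeps its sign. In the main setting the Nodal and TGF-beta targets list had a median of -0.002 and an upward test direction. Its median stayed negative in each setting below. The primed epiblast and glycolysis lists had main medians of -0.121 and -0.059, so their values of -0.091 and -0.016 below kept the sign. With quantile normalization the values were Pou5f1 -0.022, mitochondrial respiratory chain list -0.019, G1/S cell cycle list -0.034 and Nodal and TGF-beta targets list -0.02. With the planned normexp correction the values were Pou5f1 -0.271, Sox2 -0.117, Stat3 -0.252, Cyp26a1 0.395, Rarb 0.126 and Crabp2 0.713. That correction also gave Gata6 0.415, Krtap6-2 0.92, Fgf10 0.814, Cacna1g 0.412, Clec10a 0.876, Lratd2 0.347 and Rflna 0.58. Further values under it were Zfp352 0.69, Tcstv3 0.166, Igf2 0.386, Col1a1 0.301, Atf3 0.148, Fas 0.701 and Psmb8 0.084. That correction also gave Oasl2 0.424, Cdc20 -0.15, Cyp26b1 0.579, Foxa1 0.689, Cdx1 0.732, Hoxb7 0.361 and Amn 0.146. Further values under it were Hand2 0.882, Fgf8 0.426, Map2 0.763, Msx2 0.555, Id2 0.086, Rnf43 0.163 and Sp5 0.239. That correction also gave Gpr182 0.845, Hlf 0.564, naive pluripotency list -0.015, general pluripotency list -0.067, primed epiblast list 0.003, LIF and STAT3 targets list -0.016 and DNA methylation and TET machinery list -0.206. Further values under it were histone demethylases list -0.191, mitochondrial respiratory chain list -0.288, NRF2 and antioxidant genes list -0.114, interferon response list 0.177, G1/S cell cycle list -0.238, G2/M cell cycle list -0.287 and retinoid metabolism and receptors list 0.239. That correction also gave retinoic-acid-responsive genes list 0.395, Hox paralogs 1 to 5 list 0.803, Hox paralogs 6 to 13 list 0.767, primitive endoderm list 0.65, primitive streak and mesoderm list 0.703, neuroectoderm list 0.422 and Nodal and TGF-beta targets list -0.272. Further values under it were BMP targets list 0.165 and Wnt targets list 0.239. With the authors' series values the values were Pou5f1 -0.022, Dppa3 0.182, mitochondrial respiratory chain list -0.016, G1/S cell cycle list -0.033 and Nodal and TGF-beta targets list -0.019. With slide block the values were Pou5f1 -0.046 and Nodal and TGF-beta targets list -0.014. Without ddH2O replicate 1 the values were Pou5f1 -0.033, Socs3 0.012 and Gata6 0.015. Without ddH2O replicate 2 the values were Pou5f1 -0.028 and Nodal and TGF-beta targets list -0.016. Without VC replicate 1 the values were Pou5f1 -0.019, Gata6 0.036, glycolysis list -0.016 and Nodal and TGF-beta targets list -0.01. With median scaling the value was Socs3 0.024. With array weights the value was Socs3 0.041. With spike-in scaling the values were Socs3 0.063 and Gata6 0.034. Without ddH2O replicate 3 the value was Socs3 0.021. Without VC replicate 2 the values were Socs3 0.187, Stra8 0.047 and primed epiblast list -0.091. With mean of the probes of a gene the value was Gata6 0.02. With no filter on dim probes the value was Nodal and TGF-beta targets list -0.005. With normexp without spots of high local background the value was Nodal and TGF-beta targets list -0.016. Without VC replicate 3 the value was Nodal and TGF-beta targets list -0.007.

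Directions that turned in RA are given as log2 differences, for a list as its median, where the direction is that of the test. With median scaling the values were Stat3 -0.17 and Dazl -0.042. With the planned normexp correction the values were Stat3 -0.074, Zfp36 0.331, Mesp1 0.321, Fbln5 0.248, Gpr182 0.221 and Hlf 0.149. With mean of the probes of a gene the value was Stat3 -0.192. With array weights the value was Stat3 -0.017. With normexp without spots of high local background the values were Stat3 -0.074, Zfp36 0.331, Mesp1 0.321, Fbln5 0.248, Gpr182 0.221 and Hlf 0.149. With spike-in scaling the values were Stat3 -0.356, Dazl -0.228, Txnrd1 -0.177, Tyms -0.067 and Acvr2b -0.031. Without DMSO replicate 3 the value was Stat3 -0.01. Without RA replicate 3 the value was Stat3 -0.039. With stricter filter on dim probes the value was Wnt targets list -0.449.

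For the results that turned with a sample left out, the ranges over the samples left out in VC were Pou5f1 -0.033 to 0.126, Socs3 -0.108 to 0.187, Stra8 -0.199 to 0.047 and Gata6 -0.074 to 0.036. The list medians ranged from -0.15 to -0.068 for primed epiblast, -0.09 to -0.016 for glycolysis and -0.016 to 0.028 for Nodal and TGF-beta targets. The medians of primed epiblast and glycolysis stayed negative, and only their test direction turned. In RA, Stat3 ranged from -0.039 to 0.064.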

Other observations

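Of 1446 regions on the RA design with at least 3 tested probes and no gene symbol here, every probe was higher in RA in 276 and lower in 212. In coordinates of the array files (mm9), 3 probes at chromosome X from 123303474 to 123305531 were higher by a mean log2 difference of 7.12, and 4 probes at chromosome 3 from 75451370 to 75459674 had a mean log2 difference of -7.24. These regions were chosen after their values were seen, as those with the largest mean rise and fall among regions where every probe was called in one direction.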
